A study of Homo sapiens with 18 samples.

How the data were processed

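MDA-MB-231 cells were profiled by the authors on Agilent whole human genome arrays of 45015 features, of which 43376 were not controls and 41000 were distinct probes. Each of the 18 deposited files holds the Cy5 and Cy3 signal intensity of every feature, extracted with Agilent Feature Extraction 9.5.3.1 per the file headers. Per the file headers, the software corrected these intensities for background and dye bias and formed the LogRatio column, the log10 of the processed Cy5 signal over the processed Cy3 signal. The deposited series table holds the same log10 ratios rounded by the authors, since it differed from LogRatio by at most 0.005 in every file. Numbers in the files are written with decimal commas and were read as such.

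Groups followed the labels: 9 Gy at 24 h against untreated cells, 23 Gy at 24 h against untreated cells, and RCF cells at 7 d after 9 Gy against 9 Gy at 24 h, with 6 files each. Cy5 always carried the first RNA and Cy3 the second, so no dye swap was available. The 6 files of a group turned out to be 3 scans of each of 2 arrays. Pairs of files of the same array shared between 66.7% and 100.0% of the spots marked as non-uniform, pairs of files of both arrays of a group shared at most 2.5%, and pairs across groups shared 0.0%. The log ratios of the 3 scans were therefore averaged, which left n = 2 arrays per group, 6 arrays in all. This step was chosen after the data had been seen, in place of a planned fit with every file as a replicate. The arrays lay on 2 slides, slide 1 with both dose groups and slide 2 with the RCF group. The p-values measure the spread between arrays alone, which may be technical, because the labels do not say whether the arrays of a group held separate cultures. A co-hybridised control RNA has no spread of its own in such a ratio. Replicate numbers do not pair files across groups: residual log ratios of files with the same number had a median r of 0.0279 (range -0.183 to 0.169), files with other numbers one of -0.00212, and 4 of 18 files matched best with a file of their own number.

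Mean signals were corrected for local background with normexp and an offset of 50, and log2 ratios were normalised by loess within arrays, with no normalisation between arrays, using limma 3.58.1 in R 4.3.3, with files read by data.table version 1.17.8. Probes were kept if well above background in at least 1 channel in at least 6 of the 18 files, which left 33240 probes (81.1%). Names came from the RefSeq gene table of assembly GRCh38.p14, used for names alone: 23434 probes matched by accession, 2317 by symbol and 1040 by an older symbol, and 14209 kept the name in the file. The build in the file headers is older, and no coordinates are given. The brightest probe stood for each name, which gave 25042 names tested, 15377 of them with a reference gene. At several probes per gene, the mean of the other probes had the sign of the called value for 74.3% of genes at 9 Gy, 69.3% at 23 Gy, 78.8% in RCF cells and 73.5% between the doses. Signal over background limits dim genes, and the number of arrays limits the precision of every value.

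A single linear model with 1 mean per group and 3 residual degrees of freedom was fitted with limma, followed by eBayes (prior degrees of freedom 2.53, prior SD of 0.0631), and tests were two-sided with Benjamini-Hochberg adjustment over all names tested. The comparisons were each group ratio against 0, the difference between the 23 Gy and 9 Gy ratios, and the sum of the 9 Gy and RCF ratios, an indirect comparison of RCF with untreated cells that was used for lists and named genes alone. A name was called at an adjusted p under 0.05, and counted as 2-fold at an absolute log2 ratio of at least 1. Because 2 arrays per group form no group large enough for it, Dixon's test of extreme samples was not applied, and other splits of the samples were not counted. The same RNAs were also compared in 1 dye between arrays (single-channel values after Aquantile), as a check on dye effects. In every contrast but that of the doses this set the RCF arrays on slide 2 against arrays on slide 1, so a value that turned or a call that was lost there can stem from the slide as well as from the dye. The comparison of the doses stayed within slide 1. Each same-dye value also reused a channel of the ratio it was set beside, such as Cy3 of the 9 Gy arrays at 9 Gy. Agreement in sign for genes called by that ratio is therefore partly built in. The same-dye value at 23 Gy was the one at 9 Gy plus the difference between the doses. As a further check, untreated RNA of the 23 Gy arrays was tested against that of the 9 Gy arrays in Cy3, which gave 0 names at an adjusted p under 0.05, 1003 at an unadjusted p under 0.05, and an SD of log2 differences of 0.0864. A dye effect of a probe cancels in that test.

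The 26 gene lists, 4 of them meant as checks, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists were p53 targets, G2/M and mitosis, G1/S and DNA replication, homologous recombination and crosslink repair, end joining, replication-dependent histones, interferon-stimulated genes, inflammatory secretory genes, immediate early and AP-1, apoptosis regulators, epithelial-mesenchymal and matrix, TGF-beta responsive, cholesterol synthesis, unfolded protein and amino acid stress, hypoxia and glycolysis, NRF2 antioxidant, MHC class I presentation, lysosome, oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, breast cancer stem cell markers, and luminal epithelial, fibroblast, blood cell and housekeeping genes. Some list members, such as CMPK2, NDUFA4 and RPSA, had no probe of that name, and H2AC16, H4C5, CXCL6, EGR3, MMP2, ALDH1A1, PROM1, LGR5, PGR, POSTN, HBB and MS4A1 were removed by the filter. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison, with camera at an estimated correlation and with fry beside it. With an estimated correlation camera refers its statistic to the 3 residual degrees of freedom, so a lost call can reflect low power alone. Named genes were the 10 largest rises and 10 largest falls of each comparison within arrays among called genes with a known symbol, 1 direction in every file and a signal above background, and the 5 largest each way between the doses. Up to 4 members with the largest change per list and comparison, and members of the p53, inflammatory and interferon lists, were also eligible.

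Data were simulated with the same design, a spread per gene drawn from the eBayes prior, and 24906 genes. In them, log2 changes of 0.5, 1 and 2 were called in 72%, 94% and 98% of changed genes for 9 Gy, with 10.4% of calls false. For 23 Gy the shares were 88%, 96% and 100%, with 2.47% false. For RCF cells they were 82%, 94% and 100%, with 3.23% false, and between the doses 48%, 92% and 96%, with 4.8% false. A log2 change of 0.25 was called in 8% of changed genes for 9 Gy, 14% for 23 Gy, 8% for RCF cells and 0% between the doses. All groups were given the same spread, whereas the measured RCF arrays had unequal SDs of log2 ratios (0.245 and 0.417). In each of these comparisons a list of genes shifted by 0.3 was called and 0 of 25 other lists were. Genes were simulated independently of each other, whereas the correlation estimated within lists reached 0.677, for inflammatory secretory genes. The simulation thus cannot tell how often camera calls a list of correlated genes falsely. Correlations of log2 ratios across genes were set beside 100 simulations of unchanged groups that share a control RNA. In these, each RNA and the array noise of each group mean were assumed to vary equally, and no dye effect was simulated. The assumption of equal variation fixes the simulated r, whatever the measured ratios are.

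Alternatives tried were the software's processed signals, no background subtraction, an offset of 16, the LogRatio column and the series table as given, median centring, scaling between arrays, no filter and a stricter filter, the mean of all probes of a gene, each group fitted alone, the replicate number as a block, eBayes with trend and robust settings, array weights, leaving out each array, and the same-dye comparison. Added after the data had been seen were the 18 files as separate replicates, the array as a random block, the first scan of each array, and a fit on slide 1 alone. A random block by slide was not run, since each group lay on 1 slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.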

Results

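Gene expression was measured in MDA-MB-231, a human triple-negative breast cancer cell line that carries mutant p53, on Agilent whole human genome arrays that compare a Cy5-labelled RNA with a Cy3-labelled RNA. The 18 deposited scans form 3 groups of 6. In the first group, RNA taken 24 h after 9 Gy of electron irradiation was compared with RNA of untreated cells, and in the second, RNA taken 24 h after 23 Gy was compared with RNA of untreated cells. In the third, RNA of cells named RCF, taken 7 d after 9 Gy, was compared with RNA taken 24 h after 9 Gy. The labels do not spell out RCF. The 6 scans of each group came from 2 arrays scanned 3 times each, so each mean rests on n = 2 arrays and errors are standard errors (SE) between arrays. The spread behind each SE was shared by the 3 groups, so an SE can understate the difference between the RCF arrays. Of the 45015 features of a scan, between 76.0% and 81.1% of the probe spots were well above background in Cy5 and between 71.3% and 76.1% in Cy3. After a filter on dim probes, 25042 gene and transcript names were tested, 15377 of which belong to a reference gene.

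At 24 h after 9 Gy, 24 of 30 transcripts of replication-dependent histones, the proteins that package newly made DNA, were lower than in untreated cells, and the call of the list did not hold with an estimated correlation (adjusted p = 0.308). H4C14, which encodes histone H4, had the largest fall among the named genes, with a log2 ratio of -1.54 ± 0.05 (SE, n = 2 arrays, 2.90-fold lower, adjusted p = 0.000953). Of 30 genes of G2/M and mitosis 18 were higher, among them CCNB1, which encodes cyclin B1, at 0.52 ± 0.03 (adjusted p = 0.00158). The call of this list did not hold with an estimated correlation either (adjusted p = 0.308). That test has only 3 residual degrees of freedom, so a lost call cannot tell correlation between genes from low power. CDKN1A, the p53 target that blocks the cell cycle, was not called, at 0.02 ± 0.08 (adjusted p = 0.987). The largest rise among the named genes was that of HES1, a transcriptional repressor that acts downstream of Notch, at 1.30 ± 0.07 (adjusted p = 0.00138).

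The comparison of 9 Gy with untreated cells asks which transcripts high dose irradiation changed, the subject of the series. Limma called 3815 names changed, 2061 up and 1754 down, and 20 of them changed at least 2-fold, 3 up and 17 down. With either of the 2 arrays left out, 140 or 316 names were called. All 20 had the same sign when RNAs in the same dye were compared between arrays. In every contrast but that of the doses this set slide 2 against slide 1, so that slide and dye effects cannot be told apart there. It also reused the Cy3 signal of the 9 Gy arrays, so the agreement in sign is partly built in. That comparison itself called 2245 up and 4199 down, and 251 up and 22 down at least 2-fold, and the software's own log ratios gave 329 up and 222 down at least 2-fold. After the log ratios were scaled between arrays, 79 rose and 101 fell at least 2-fold, and with arrays centred on their median limma called 0 names, with 3044 at an unadjusted p under 0.05. Besides HES1, the largest rises were those of the AP-1 gene FOSB (1.09 ± 0.23), the MAP kinase phosphatase DUSP1 (1.03 ± 0.04), SYN1 (1.00), ZNF575 (0.93), SELENBP1 (0.87), the transcription factor EGR1 (0.85 ± 0.05), LINC02907 (0.84), CRTC1 (0.80) and FOS (0.79 ± 0.19). Other probes of SYN1, ZNF575, SELENBP1 and CRTC1 read 0.02, -0.16, 0.08 and 0.04, and the other probes of HES1 read 1.48 and 0.16. Besides H4C14, the largest falls were those of the histone genes H4C8 (-1.48), H4C9 (-1.33), H4C6 (-1.32), H4C2 (-1.27), H2BC26 (-1.18), H2BC5 (-1.17) and H4C3 (-1.13), then LARS1 (-1.11) and MALAT1 (-1.07). Histone genes of a class are alike in sequence, so a value for 1 of them can include others. The other probes of H2BC26 and H2BC5 read -0.68 and -0.43. The other probe of LARS1 read -0.15, and those of MALAT1 read -0.11, -0.05 and 0.04.

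Of the 26 gene lists, camera called 9 at 9 Gy. Among 30 replication-dependent histones 0 rose, 24 fell and 6 did not pass (28 fell adjusted over the list alone). Their median log2 ratio was -0.64 (adjusted p = 2.17e-25, adjusted p = 0.308 with an estimated correlation). Among 30 genes of G2/M and mitosis 18 rose, 0 fell and 12 did not pass (20 and 1 adjusted over the list alone). This list had a median of 0.26 (adjusted p = 9.03e-11, adjusted p = 0.308 with an estimated correlation), led by HMMR (0.64), KIF2C (0.58) and TOP2A (0.54). Among 32 genes of G1/S and DNA replication 0 rose and 9 fell (3 and 11 adjusted over the list alone). The median came to -0.09, which turned to 0.18 when arrays were centred on their median (adjusted p = 0.00505, adjusted p = 0.607 with an estimated correlation). The replicative helicase genes MCM6 (-0.69) and MCM5 (-0.62) fell most in it. Among 24 genes of cholesterol synthesis 0 rose and 8 fell (2 and 9 adjusted over the list alone). Their median stood at -0.10, which turned to 0.19 under median centring (adjusted p = 0.000792, adjusted p = 0.689 with an estimated correlation), and INSIG1, which holds back sterol synthesis, fell most (-0.81). Among 31 interferon-stimulated genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.000254, adjusted p = 0.791 with an estimated correlation), led by ISG20 (0.74) and IFIT1 (0.59). Among 17 genes of MHC class I presentation 9 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was 0.20, against -0.02 between RNAs in the same dye on different slides (adjusted p = 6.48e-05, adjusted p = 0.609 with an estimated correlation), and the peptide transporter gene TAP1 rose most (0.64). Among 24 lysosomal genes 5 rose and 0 fell (6 and 0 adjusted over the list alone). This list had a median of 0.12 (adjusted p = 0.00733, adjusted p = 0.791 with an estimated correlation). Among 39 cytosolic ribosomal protein genes 7 rose and 1 fell (13 and 1 adjusted over the list alone). Here the median came to 0.10, against -0.04 in the same dye on different slides (adjusted p = 0.0049, adjusted p = 0.791 with an estimated correlation). Among 28 genes of oxidative phosphorylation 1 rose and 4 fell (2 and 6 adjusted over the list alone). Their median stood at -0.05, which turned to 0.32 under median centring (adjusted p = 0.044, adjusted p = 0.791 with an estimated correlation).

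Of the 9 calls, 5 were also made between RNAs in the same dye, where G1/S and DNA replication (adjusted p = 0.0512), lysosome (adjusted p = 0.103, median 0.07), MHC class I presentation (adjusted p = 0.878) and ribosomal proteins (adjusted p = 0.702) did not pass. The remaining lists did not pass camera's test at 9 Gy. Of 30 p53 targets 4 rose and 3 fell (4 and 5 adjusted over the list alone), and the rise of BBC3 (0.71 ± 0.11), which triggers apoptosis, stood beside falls of GDF15 (-0.44 ± 0.09) and PMAIP1 (-0.39 ± 0.07). Of 34 inflammatory secretory genes 0 rose and 1, the cytokine gene IL11 (-0.30, turned to 0.09 under median centring), fell, both overall and adjusted over the list alone. This count rests on a spread shared with the RCF arrays, and the same-dye comparison called 3 of these genes up and 3 down. Of 26 immediate early and AP-1 genes 8 rose and 5 fell (9 and 6 adjusted over the list alone). Rises and falls numbered 7 and 2 of 28 apoptosis regulators, 4 and 1 of 28 genes of homologous recombination and crosslink repair, and 3 and 0 of 14 end joining genes. They numbered 1 and 5 of 26 genes of unfolded protein and amino acid stress, 2 and 5 of 25 of hypoxia and glycolysis, 1 and 2 of 22 NRF2 antioxidant genes, and 2 and 5 of 29 of ribosome biogenesis and MYC targets. They numbered 2 and 2 of 29 epithelial-mesenchymal and matrix genes, 0 and 2 of 22 TGF-beta responsive genes, and 4 and 2 of 19 breast cancer stem cell markers. Among the lists meant as checks, they numbered 2 and 0 of 19 luminal epithelial markers, 1 and 0 of 13 fibroblast markers, 1 and 0 of 13 blood cell markers, and 1 and 1 of 16 housekeeping genes. The median and camera's direction had opposite signs for p53 targets (0.02) and TGF-beta responsive genes (0.01), and the median and mean did for TGF-beta responsive and for housekeeping genes (-0.03).

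At 24 h after 23 Gy, all 30 measured replication-dependent histone genes fell. Of 29 genes of ribosome biogenesis and MYC targets 20 fell, with a list median that turned positive under median centring and a call that did not hold with an estimated correlation (adjusted p = 0.209). H2AC1, which encodes histone H2A, had the largest fall, at -2.45 ± 0.13 (SE, n = 2 arrays, 5.47-fold lower, adjusted p = 0.000264). The largest rise was that of GINS4, a subunit of the replicative helicase complex, at 2.25 ± 0.09 (4.76-fold higher, adjusted p = 0.000178), although its second probe read 1.08. CNN1, which encodes the smooth muscle protein calponin 1, rose by 1.98 ± 0.32 (adjusted p = 0.00607). CDKN1A rose by 0.52 ± 0.08 (adjusted p = 0.00608), while MDM2, the ubiquitin ligase that removes p53, fell by 0.48 ± 0.05 (adjusted p = 0.00187).

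The comparison of 23 Gy with untreated cells asks the same question at the higher dose. Limma called 9595 names changed, 4955 up and 4640 down, and 179 of them changed at least 2-fold, 37 up and 142 down. With either array left out, 3409 or 2770 names were called. Between RNAs in the same dye 2968 were called up and 4458 down, and 233 rose and 114 fell at least 2-fold. With arrays centred on their median, 429 rose and 31 fell at least 2-fold, and the median log2 ratio of all genes moved from 0.01 to 0.17. After the log ratios were scaled between arrays, 1 rose and 5 fell at least 2-fold, and in the software's own log ratios 674 rose and 399 fell. The remaining largest rises were those of ZNF652 (1.58), the death receptor gene TNFRSF25 (1.34 ± 0.18), LAT2 (1.28), DMBT1 (1.26), DUSP1 (1.25), LCP1, which bundles actin (1.17), BPNT1 (1.16) and the proteoglycan gene CSPG4 (1.14 ± 0.19). The other probes of LAT2 and BPNT1 read 0.30 and 0.26. After H2AC1 the falls ran through H4C14 (-2.30 ± 0.05), H4C8 (-2.27), H4C2 (-2.26), H4C13 (-2.19), H4C9 (-2.16), H2BC26 (-2.12), H4C6 (-2.07), H2BC5 (-2.01) and H4C3 (-1.89). The other probes of H2BC26 and H2BC5 read -1.385 and -1.019.

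Camera called 6 of the 26 lists at 23 Gy. Among 30 replication-dependent histones 0 rose, 30 fell and 0 did not pass (30 fell adjusted over the list alone), with a median log2 ratio of -1.20 (adjusted p = 2.07e-20, adjusted p = 0.412 with an estimated correlation). Among 29 genes of ribosome biogenesis and MYC targets 1 rose and 20 fell (1 and 22 adjusted over the list alone). Their median was -0.27, which turned to 0.21 under median centring (adjusted p = 3.18e-07, adjusted p = 0.209 with an estimated correlation), and UTP20, which processes ribosomal RNA, fell most (-1.31 ± 0.07). Among 32 genes of G1/S and DNA replication 5 rose and 14 fell (5 and 18 adjusted over the list alone). As a list they had a median of -0.20, which turned to 0.30 under median centring (adjusted p = 0.00259, adjusted p = 0.479 with an estimated correlation). The largest falls in it were those of MCM5 (-1.22) and the cell cycle transcription factors E2F2 (-1.14) and E2F1 (-0.98). Among 31 interferon-stimulated genes 17 rose and 0 fell (17 and 0 adjusted over the list alone). The median came to 0.35 (adjusted p = 3.02e-05, adjusted p = 0.936 with an estimated correlation), led by IFI44 (0.86 ± 0.04), ISG20 (0.82), the interferon signalling factor IRF9 (0.71) and OASL (0.69). Among 30 genes of G2/M and mitosis 17 rose and 5 fell (20 and 6 adjusted over the list alone). Their median stood at 0.19 (adjusted p = 0.012, adjusted p = 0.607 with an estimated correlation). Among 17 genes of MHC class I presentation 11 rose and 3 fell (11 and 3 adjusted over the list alone), with a median of 0.17, against -0.09 in the same dye on different slides (adjusted p = 0.0447, adjusted p = 0.936 with an estimated correlation).

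Between RNAs in the same dye 5 of these 6 calls were made at 23 Gy, and MHC class I presentation did not pass (adjusted p = 0.817). Of the lists that did not pass at 23 Gy, 8 of 30 p53 targets rose and 5 fell (8 and 5 adjusted over the list alone), and 6 of 34 inflammatory secretory genes rose and 1 fell (5 and 1 adjusted over the list alone). The collagenase gene MMP1 (0.65) and the cytokine gene CSF2 (0.57 ± 0.11) rose most among the latter, while IL6 at 0.60 ± 0.32 did not pass (adjusted p = 0.202). IL6 read 0.56 and 0.63 on the 23 Gy arrays, and its SE stems mostly from the spread shared with the RCF arrays (2.00 and 3.51). Rises and falls numbered 13 and 3 of 28 genes of homologous recombination and crosslink repair, 4 and 3 of 14 end joining genes, 10 and 6 of 26 immediate early and AP-1 genes, and 9 and 3 of 28 apoptosis regulators. They numbered 8 and 5 of 29 epithelial-mesenchymal and matrix genes, 4 and 4 of 22 TGF-beta responsive genes, 5 and 9 of 24 of cholesterol synthesis, and 3 and 12 of 26 of unfolded protein and amino acid stress. They numbered 2 and 11 of 25 of hypoxia and glycolysis, 0 and 7 of 22 NRF2 antioxidant genes, 9 and 3 of 24 lysosomal genes, 5 and 6 of 28 of oxidative phosphorylation, and 8 and 3 of 39 cytosolic ribosomal protein genes. They numbered 5 and 3 of 19 breast cancer stem cell markers, 3 and 6 of 19 luminal, 1 and 1 of 13 fibroblast and 3 and 1 of 13 blood cell markers, and 5 and 4 of 16 housekeeping genes. ACTA2, the smooth muscle actin gene of the fibroblast list, rose by 1.09 ± 0.06 (adjusted p = 0.000255). Median and mean had opposite signs for TGF-beta responsive genes, end joining, oxidative phosphorylation and housekeeping genes, with medians of -0.02, 0.04, 0.03 and -0.02.

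Between the doses, 10 of 29 genes of ribosome biogenesis and MYC targets and 17 of 30 histone genes were lower after 23 Gy than after 9 Gy. Neither list was called with an estimated correlation (adjusted p = 0.107 and 0.512), and the median of histones, -0.60, turned to 0.65 after scaling between arrays. UTP20 was lower, with a log2 difference of -1.02 ± 0.11 (SE, n = 2 arrays per dose, adjusted p = 0.0158), and HES1, which had risen at 9 Gy, was lower too, at -1.47 ± 0.10, with -1.50 and -0.17 at its other probes. GINS4 was higher after 23 Gy, at 2.24 ± 0.13 (adjusted p = 0.0104), with 1.09 at its second probe. LMNB1, which encodes the nuclear envelope protein lamin B1, differed by 1.32 ± 0.15 (adjusted p = 0.0176), mostly because it had fallen at 9 Gy. It read -1.04 and -1.03 on the 9 Gy arrays against 0.29 on both 23 Gy arrays, where it was not called.

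Limma called 1672 names different between 23 Gy and 9 Gy, 752 higher and 920 lower at 23 Gy, and 20 of them differed at least 2-fold, 15 higher and 5 lower. With 1 of the 4 arrays left out, between 0 and 2 names were called. Under median centring limma called 0 names, with 3108 at an unadjusted p under 0.05, and after scaling between arrays 1. ZNF652 (1.45), FBXO34 (1.41) and HNRNPA0 (1.27) completed the 5 largest positive differences, with 0.11 and -0.22 at the other probes of FBXO34 and 0.54 at that of HNRNPA0. HNRNPA0 read -0.80 and -0.73 on the 9 Gy arrays and 0.51 and 0.50 on the 23 Gy arrays, so most of its difference was a fall at 9 Gy. FBXO34 also fell at 9 Gy, by 0.42, and rose by 0.99 at 23 Gy. The largest negative differences included the transcription factor MYB (-1.15), H2AC1 (-1.49 ± 0.18) and H4C2 (-0.99), the last pair turning to 0.26 and 1.53 after scaling between arrays.

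Camera called 3 of the 26 lists between the doses. Among 30 replication-dependent histones 0 were higher and 17 lower at 23 Gy (27 lower adjusted over the list alone). Their median log2 difference was -0.60, which turned positive after scaling between arrays (adjusted p = 3.13e-17, adjusted p = 0.512 with an estimated correlation). Among 29 genes of ribosome biogenesis and MYC targets 0 were higher and 10 lower (20 lower adjusted over the list alone). This list had a median of -0.23 (adjusted p = 2.22e-11, adjusted p = 0.107 with an estimated correlation). Among 31 interferon-stimulated genes 4 were higher and 0 lower (5 and 0 adjusted over the list alone). The median came to 0.14, which turned to -0.04 after scaling between arrays (adjusted p = 0.00123, adjusted p = 0.94 with an estimated correlation), and OAS3, a sensor of double-stranded RNA, differed most (0.55). Differences in the other lists were not called. Among them, 0 of 30 genes of G2/M and mitosis were higher and 5 lower, 2 of 32 of G1/S were higher and 6 lower, and 1 of 30 p53 targets was higher and 1 lower.

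In RCF cells, 7 d after 9 Gy, 19 of 34 inflammatory secretory genes were higher than in cells 24 h after the same dose and 1 was lower, and the call of the list did not hold with an estimated correlation (adjusted p = 0.462). CXCL1, a chemokine that attracts neutrophils, was higher by 5.23 ± 0.24 (SE, n = 2 arrays, 37.5-fold, adjusted p = 0.000204), and the cytokine gene IL6 by 2.75 ± 0.32 (6.74-fold, adjusted p = 0.00262). IL6 read 2.00 and 3.51 on the 2 arrays. GDF15, a stress-induced cytokine and p53 target, was higher by 3.86 ± 0.09 (14.6-fold, adjusted p = 6.9e-05). Of 30 genes of G2/M and mitosis 27 were lower, among them the mitotic kinase PLK1, at -1.08 ± 0.04 (adjusted p = 0.00015), and of 32 genes of G1/S and DNA replication 21 were lower and 1 higher. Neither list was called with an estimated correlation (adjusted p = 0.152 for both). HLA-C, a class I antigen presentation molecule, was higher by 2.17 ± 0.04 (4.49-fold, adjusted p = 4.99e-05).

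The comparison of RCF cells with cells at 24 h after 9 Gy sets the later time point against the earlier. Time cannot be told apart in it from whatever else the name RCF stands for. Limma called 6804 names changed, 3504 up and 3300 down, and 327 of them changed at least 2-fold, 287 up and 40 down. With the RCF group fitted alone limma called 0 names, with 5930 at an unadjusted p under 0.05, so these calls rest on the spread shared with the other groups. With arrays centred on their median, 86 rose and 1 fell, and after scaling between arrays 969 rose and 408 fell. The 2 RCF arrays had unequal spreads of log2 ratios, with SDs of 0.245 and 0.417, and 785 or 197 names changed at least 2-fold, and 14450 or 5701 in all, when the first or the second was left out. SAA1, an acute phase protein (4.01 ± 0.12), the cytokine IL1B (3.85 ± 0.38), SAA2 (3.47), CXCL2 (3.43 ± 0.30), MMP1 (3.38 ± 0.13), CST1 (3.35), S100P (3.30) and TXNIP, which restrains glucose uptake (3.14 ± 0.04), completed the 10 largest rises. The other probe of SAA2 read 0.08 and that of CXCL2 read 2.12. The largest falls were those of SPC25, a kinetochore protein (-1.67 ± 0.04), H4C2 (-1.47), HMGB1P1 (-1.43), FOS (-1.41 ± 0.19), ARG2 (-1.40), H4C13 (-1.39), HMGB1 (-1.38), HES1 (-1.25), LMNB1 (-1.22 ± 0.11) and NPRL3 (-1.16). The other probes of HMGB1 read -1.13, -1.06 and -1.29, and that of NPRL3 read -0.12.

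Camera called 17 of the 26 lists in RCF cells. Among 34 inflammatory secretory genes 19 rose, 1 fell and 14 did not pass (28 and 1 adjusted over the list alone). Their median log2 ratio stood at 0.78 (adjusted p = 3.44e-09, adjusted p = 0.462 with an estimated correlation). The list included rises of CXCL8 (2.51 ± 0.45), NFKBIA, the inhibitor of NF-kappaB (2.42 ± 0.06), ICAM1 (2.16) and BIRC3 (2.11). CXCL8 read 1.46 and 3.57 on the 2 RCF arrays. Among 30 genes of G2/M and mitosis 0 rose and 27 fell (0 and 29 adjusted over the list alone), with a median of -0.54 (adjusted p = 7.38e-16, adjusted p = 0.152 with an estimated correlation), and CDC20, which starts anaphase, fell most (-1.16). Among 32 genes of G1/S and DNA replication 1 rose and 21 fell (2 and 23 adjusted over the list alone). Their median was -0.39 (adjusted p = 2.25e-08, adjusted p = 0.152 with an estimated correlation). Among 28 genes of homologous recombination and crosslink repair 1 rose and 18 fell (1 and 21 adjusted over the list alone). This list had a median of -0.32 (adjusted p = 1.24e-08, adjusted p = 0.452 with an estimated correlation). Among 24 lysosomal genes 22 rose and 0 fell (23 and 0 adjusted over the list alone). Here the median came to 0.51 (adjusted p = 8.94e-12, adjusted p = 0.406 with an estimated correlation), led by PSAP, the precursor of sphingolipid activators (1.41). Among 17 genes of MHC class I presentation 12 rose and 0 fell (13 and 0 adjusted over the list alone). Their median stood at 0.70 (adjusted p = 9.01e-08, adjusted p = 0.364 with an estimated correlation). Among 31 interferon-stimulated genes 15 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 0.39 (adjusted p = 1e-07, adjusted p = 0.462 with an estimated correlation), led by OASL (1.95) and IFIT2 (1.83). Among 26 immediate early and AP-1 genes 18 rose and 3 fell (21 and 3 adjusted over the list alone). Their median was 0.50 (adjusted p = 6.82e-07, adjusted p = 0.406 with an estimated correlation), led by JUNB (2.32) and ATF3 (1.86). Among 30 replication-dependent histones 20 rose and 6 fell (20 and 8 adjusted over the list alone). As a list they had a median of 0.96 (adjusted p = 6.44e-05, adjusted p = 0.462 with an estimated correlation), and H2AC18 (2.22) rose most.

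Among 26 genes of unfolded protein and amino acid stress 14 rose and 3 fell in RCF cells (18 and 3 adjusted over the list alone). Here the median came to 0.41 (adjusted p = 0.000335, adjusted p = 0.462 with an estimated correlation), led by DDIT3, a stress-induced transcription factor (1.70 ± 0.28). DDIT3 read 1.05 and 2.35 on the 2 RCF arrays. Among 29 genes of ribosome biogenesis and MYC targets 2 rose and 15 fell (3 and 16 adjusted over the list alone). Their median stood at -0.16 (adjusted p = 6.44e-05, adjusted p = 0.152 with an estimated correlation). Among 25 genes of hypoxia and glycolysis 10 rose and 4 fell (13 and 4 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.00565, adjusted p = 0.55 with an estimated correlation), led by the vasodilator peptide gene ADM (1.76). Among 22 TGF-beta responsive genes 7 rose and 2 fell (10 and 2 adjusted over the list alone). Their median was 0.22 (adjusted p = 0.00587, adjusted p = 0.569 with an estimated correlation). Among 28 genes of oxidative phosphorylation 5 rose and 13 fell (5 and 14 adjusted over the list alone). As a list they had a median of -0.15 (adjusted p = 0.00695, adjusted p = 0.429 with an estimated correlation). Among 19 luminal epithelial markers 8 rose and 2 fell (8 and 2 adjusted over the list alone). The median came to 0.19 (adjusted p = 0.0384, adjusted p = 0.462 with an estimated correlation), led by AGR2 (1.82) and TFF3 (1.70). Among 28 apoptosis regulators 11 rose and 4 fell (13 and 4 adjusted over the list alone). Their median stood at 0.14 (adjusted p = 0.0409, adjusted p = 0.535 with an estimated correlation). Among 29 epithelial-mesenchymal and matrix genes 9 rose and 2 fell (11 and 5 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.0425, adjusted p = 0.535 with an estimated correlation). Between RNAs in the same dye 14 of the 17 calls were made, and luminal markers (adjusted p = 0.105, median 0.10), epithelial-mesenchymal and matrix genes (adjusted p = 0.0715) and oxidative phosphorylation (adjusted p = 0.0506) did not pass. Of the lists that did not pass, 10 of 30 p53 targets rose and 3 fell, overall and adjusted over the list alone, and besides GDF15 the DNA damage gene GADD45A (1.69), PMAIP1 (1.31) and CDKN1A (0.71 ± 0.08) rose. Rises and falls numbered 5 and 2 of 22 NRF2 antioxidant genes, 9 and 6 of 24 of cholesterol synthesis, 2 and 6 of 14 end joining genes, 10 and 7 of 39 cytosolic ribosomal protein genes, and 4 and 5 of 19 breast cancer stem cell markers. They numbered 0 and 0 of 13 fibroblast markers, 1 and 0 of 13 blood cell markers, and 5 and 7 of 16 housekeeping genes. Median and mean had opposite signs for cholesterol synthesis, stem cell markers and housekeeping genes, with medians of -0.03, -0.02 and -0.11.

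**Figure D1:**
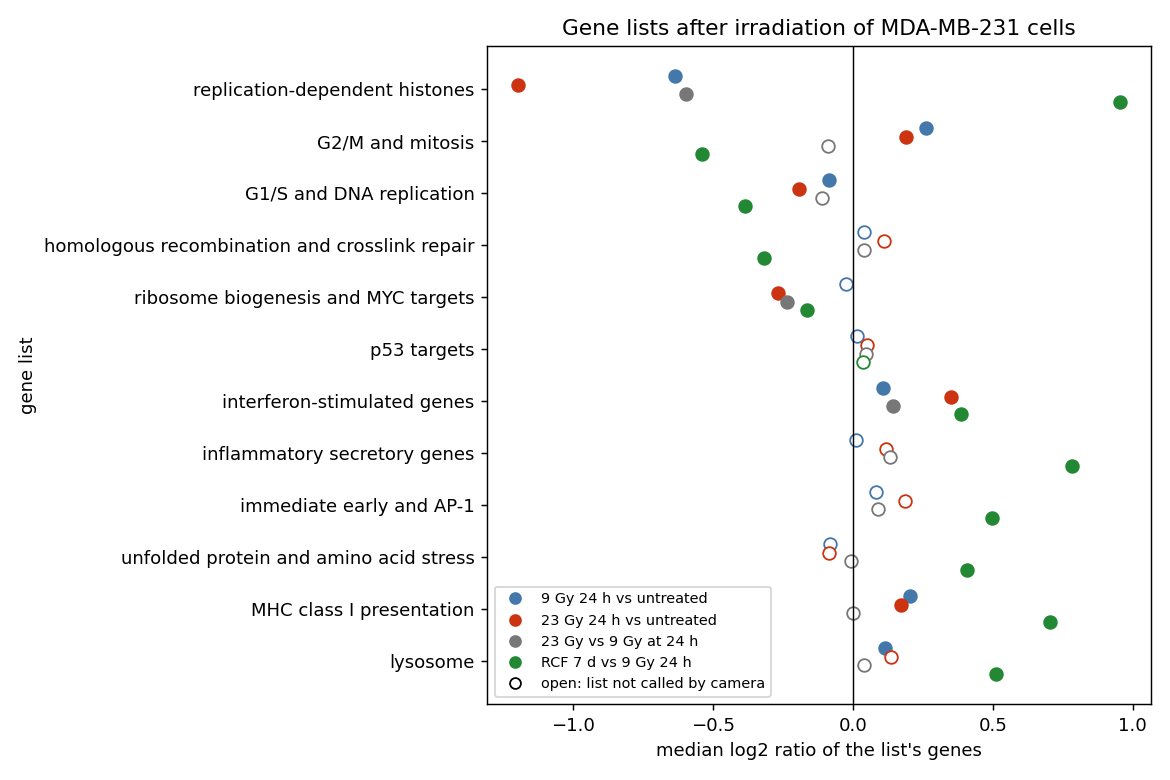
Median log2 ratio of 12 gene lists in the 3 comparisons within arrays and in the difference between 23 Gy and 9 Gy. Each point is the median of a list over n = 2 arrays per group, filled where camera called the list. Histones stood at -1.20 at 23 Gy against untreated cells, and at 0.96 in RCF cells against 9 Gy. At 9 Gy they were already lower than in untreated cells (-0.64). With an estimated correlation camera called 0 lists, histones included (adjusted p = 0.412 at 23 Gy and 0.462 in RCF cells). In the indirect contrast of RCF with untreated cells, not drawn, histones were not called (median 0.34, mean -0.05).

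**Figure D2:**
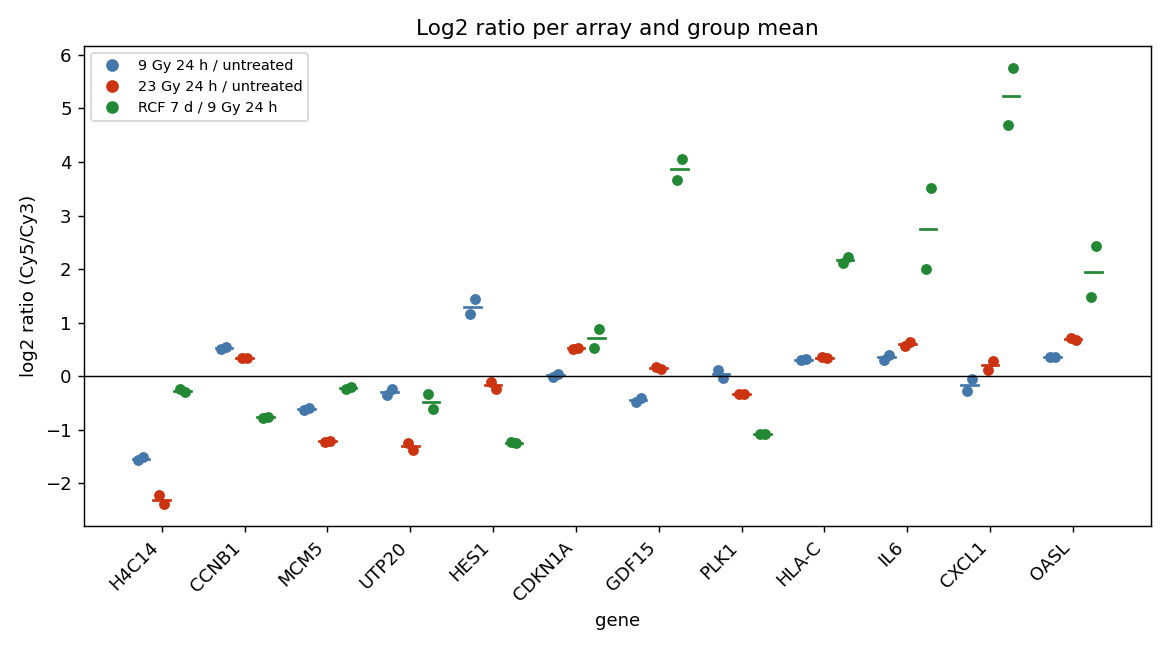
Log2 ratio of 12 genes named in the text on each of the 2 arrays of a group, with a line at their mean. CXCL1 read 4.70 and 5.76 on the RCF arrays, and H4C14 was below 0 on all 4 arrays of the dose groups.

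RCF cells were not hybridised against untreated cells, so that contrast was formed as the sum of the RCF ratio and the 9 Gy ratio, which carries any dye effect of a probe in both terms. IL6 was 8.59-fold above untreated cells (n = 2 arrays per group), a value that rests on RCF arrays with unequal readings (2.00 and 3.51). With it, 15 of 34 inflammatory secretory genes rose and 0 fell (16 and 0 adjusted over the list alone). Their median was 0.75 (adjusted p = 4.79e-08, adjusted p = 0.564 with an estimated correlation). GDF15 reached 3.42 ± 0.13, and 9 of 30 p53 targets rose and 0 fell (9 and 1 adjusted over the list alone). This list had a median of 0.10 (adjusted p = 0.0401, adjusted p = 0.564 with an estimated correlation). MHC class I presentation had a median of 1.16, with 12 of 17 genes up and 0 down (13 and 0 adjusted over the list alone), an adjusted p = 7.76e-09 and an adjusted p = 0.293 with an estimated correlation. For lysosomal genes the median was 0.68, with 19 of 24 up and 0 down (23 and 0 adjusted over the list alone), an adjusted p = 1.68e-11 and an adjusted p = 0.437 with an estimated correlation. For interferon-stimulated genes it was 0.47, with 17 of 31 up and 1 down (18 and 1 adjusted over the list alone), an adjusted p = 1.17e-08 and an adjusted p = 0.553 with an estimated correlation. Genes of G1/S and DNA replication stayed below untreated cells, with a median of -0.46, 1 of 32 up and 21 down (2 and 26 adjusted over the list alone), an adjusted p = 1.16e-10 and an adjusted p = 0.221 with an estimated correlation. Genes of G2/M and mitosis had a median of -0.21, which turned to 0.06 under median centring, with 1 of 30 up and 15 down (1 and 17 adjusted over the list alone), an adjusted p = 8.44e-07 and an adjusted p = 0.221 with an estimated correlation. Histone genes were not called, with 12 of 30 up and 11 down (14 and 12 adjusted over the list alone), a median of 0.34 and a mean of -0.05. In all, camera called 16 of the 26 lists in this contrast, 12 of them also between RNAs in the same dye. There the median of MHC class I presentation was 0.60, and p53 targets did not pass (adjusted p = 0.171, median 0.06).

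Across 25041 genes, which are not independent replicates, the log2 ratios at 9 Gy and 23 Gy correlated with r = 0.72, against r = 0.334 in 100 simulations of unchanged groups that share their control RNA, so part of the relation may stem from the shared untreated RNA. Both doses called 1541 genes up and 1487 down, an overlap that the shared untreated RNA raises by an amount not estimated, as would a dye effect. The ratio of RCF to 9 Gy had r = 0.0359 with the ratio of 9 Gy to untreated, against -0.331 in the simulations. The simulations held no dye effect, whereas all ratios had the same dye orientation. The simulated values are fixed by the assumption that each RNA and the array noise vary equally, so they are no measured background. An r above the simulated one can thus stem from dye effects or from that assumption, as well as from a shared response. Of the 3815 names called at 9 Gy, 3472 (91.0%) had the same sign in a comparison of 9 Gy with untreated RNA in the same dye on arrays not used for the ratio, again between slides, with r = 0.645 across genes. Limma's test of untreated against untreated RNA in Cy3 called 0 names, with 1003 at an unadjusted p under 0.05. A dye effect of a probe cancels in it, so it does not measure the background of the ratios, which carry that effect. In all 3 ratios 533 names were called up and 498 down, against 57.07 and 42.83 expected if calls were independent. A repeated dye effect could add to these counts, as could shared responses and shared RNA, and these were not told apart. With the correlation between genes estimated from the arrays, camera called 0 lists in each of the 5 contrasts. That test has 3 residual degrees of freedom, so a call can be lost without any correlation. Ribosome biogenesis and MYC targets, with an estimated correlation of -0.0305, moved from camera's adjusted p = 2.22e-11 to 0.107 between the doses. Fry, which tests whether the genes of a list move one way on balance, called 7 lists at 9 Gy, 7 at 23 Gy, 21 in RCF cells and 2 between the doses.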

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

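The tests of the genes higher at 23 Gy, of the histone genes and of the inflammatory genes were all chosen after the result was seen.

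Of 29 genes of ribosome biogenesis and MYC targets 10 were lower after 23 Gy than after 9 Gy, as were 17 of 30 histone genes, and GINS4 was higher. A test of the difference between the doses gave 1672 genes, 20 of them at least 2-fold. The median log2 difference was -0.60 for replication-dependent histones, 0.14 for interferon-stimulated genes and -0.23 for ribosome biogenesis and MYC targets, the 3 lists called. With an estimated correlation none of these calls held (adjusted p = 0.512, 0.94 and 0.107). After scaling between arrays the first median turned to 0.65 and the second to -0.04. The named genes that were higher at 23 Gy were GINS4 (2.24), ZNF652 (1.45), FBXO34 (1.41), LMNB1 (1.32) and HNRNPA0 (1.27). Those that were lower were H2AC1 (-1.49), HES1 (-1.47), MYB (-1.15), UTP20 (-1.02) and H4C2 (-0.99), of which H2AC1 and H4C2 turned to 0.26 and 1.53 after scaling between arrays.

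Of the 15 names at least 2-fold higher at 23 Gy, 7 are genes with a known symbol. A defect of single probes or spots was tested with other probes of the same genes, 5 probes of 4 genes. Their median log2 difference was 0.17, from -0.22 to 1.09, under the limit of 0.2 set for a defect, so a defect or another transcript form may account for part of the pattern. Among them the second probes of GINS4 (1.09) and HNRNPA0 (0.54) also read higher, which a defect of 1 probe would not give. Those of FBXO34 (0.11 and -0.22) and BPNT1 (0.17), a gene named here after its values were seen, did so little or not at all. The remaining genes had no other probe. Untreated RNA that differed between the arrays would show in Cy3, where the median difference over the 15 names was -0.05, from -0.18 to 0.04, far from the difference to be explained. A response that differs with dose stays open for GINS4 and HNRNPA0, as a hypothesis. For HNRNPA0 most of the difference was a fall at 9 Gy (-0.80 and -0.73 on its arrays).

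Of 30 histone genes 17 were lower at 23 Gy than at 9 Gy. A general stretch of the log ratios on the 23 Gy arrays would also stretch the control transcripts added to the RNAs at known ratios, and their slope at 23 Gy over that at 9 Gy was 0.984 (0.849 over 0.863). Cross-hybridisation of the transcripts of 1 histone class to all histone probes would move the classes the same way in every comparison, whereas in RCF cells against 9 Gy the class medians ran from -0.50 for H3 to 1.09 for H2B. The limits of that test were set after the values were seen. Cross-hybridisation among fewer classes was not tested. Scaling between arrays equalises the spread of log ratios, which was wider at 23 Gy (SDs of 0.264 and 0.279) than at 9 Gy (0.167 and 0.17). Under it the difference turned to 0.65, so its direction rests on not scaling. Why it turned was not tested. A dose-dependent fall stays open as a hypothesis.

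Of 34 inflammatory secretory genes 19 rose and 1 fell in RCF cells, and the call of the list did not hold with an estimated correlation (adjusted p = 0.462). A dye effect of these probes would vanish between RNAs in the same dye, where the median over the 19 called genes was 2.01 and all 19 were above 0, from 0.21 to 5.43. Over all 34 measured genes of the list, called or not, the same-dye median was 0.90. That comparison ran between slides, so a slide effect was not excluded by it. It also reused the Cy5 signal of the RCF arrays, from which the 19 genes had been called, so their agreement is partly built in. RNA of blood cells would raise their markers too, and 1 of 13 blood cell markers rose. Days in culture without irradiation cannot be told apart from the effect of irradiation, because 0 arrays held cells kept 7 d without it. Nor can either be told apart from whatever else the name RCF stands for. The RCF arrays also lay on a slide of their own, although both RNAs of the ratio were on the same arrays.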

How the results depend on the processing

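The alternatives with the 18 files as separate replicates, the array as a random block, the first scan alone and slide 1 alone were chosen after the data had been seen. Of the counts of genes past the threshold, 82 of 168 under the alternatives stayed within 1.5 times the reported count. Medians of lists kept their direction and their side of the threshold in 2039 of 2184 cases, lost a call in 62 and gained one in 69. Named genes kept both in 2204 of 2509 cases and lost the call in 291, unevenly across settings. Among 121 results for named genes, scaling between arrays ended 93 calls, median centring 62 and each group fitted alone 41. No filter, the stricter filter, the mean of all probes, and eBayes with trend and robust settings left all 8 counts within 1.5 times. The cause of a changed count was not tested unless it is given.

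In the order 9 Gy, 23 Gy, RCF and 23 Gy against 9 Gy, the software's processed signals gave 11893 changed genes at 9 Gy, 17111 in RCF cells and 4618 between the doses, and 601, 1118, 2706 and 179 changed at least 2-fold. At least 2-fold, 395 rose and 206 fell at 9 Gy, and 705 rose and 413 fell at 23 Gy. The LogRatio column gave 11909, 17637 and 4626 changed genes in the same comparisons, and 551, 1073, 2591 and 188 at least 2-fold. The series table gave 11910, 17638 and 4622, and 552, 1072, 2589 and 188 at least 2-fold. Without background subtraction the changed genes numbered 13395, 14654, 17664 and 6629, and those at least 2-fold 49 at 9 Gy and 905 in RCF cells. An offset of 16 gave 31 genes at least 2-fold between the doses.

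With median centring limma called 0 genes at 9 Gy and 0 between the doses, overall and 2-fold, with 3044 and 3108 at an unadjusted p under 0.05, while 460 changed 2-fold at 23 Gy, 87 changed in RCF cells and 82 did so 2-fold. Under it the medians turned to 0.18 for G1/S and DNA replication, 0.19 for cholesterol synthesis, 0.32 for oxidative phosphorylation, 0.37 for ribosome biogenesis and 0.41 for housekeeping genes at 9 Gy, where IL11 turned to 0.09. At 23 Gy they turned to 0.30 for G1/S and DNA replication, 0.38 for cholesterol synthesis, 0.21 for ribosome biogenesis and 0.51 for housekeeping genes. Scaling between arrays gave 180 genes at least 2-fold at 9 Gy, 1280 changed and 6 at least 2-fold at 23 Gy, 1377 and 29 in RCF cells, and 1 and 1 between the doses. It turned the difference between the doses to 0.65 for histones, -0.04 for interferon-stimulated genes, 0.26 for H2AC1 and 1.53 for H4C2. Scaling equalises the spread of log ratios, which was wider at 23 Gy. Whether that accounts for the size of these turns was not tested.

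Each group fitted alone gave 6348 changed genes at 9 Gy, 14864 at 23 Gy and 7453 between the doses. In RCF cells it gave 0 changed and 0 at least 2-fold (5930 at an unadjusted p under 0.05). The RCF arrays had r = 0.822 with each other, close to 0.842 for the 9 Gy arrays, but their SDs were unequal (0.245 and 0.417). The joint fit shares its estimate of the spread between groups. The replicate block over 18 files gave 9734, 17067, 16749 and 11245 changed genes, and 18 files as separate replicates gave 9796, 17155, 16890 and 11370, both because scans of an array were counted as replicates. The array as a random block gave 5723 at 9 Gy, 11722 in RCF cells and 4962 between the doses. Array weights gave 7817 at 9 Gy, 3648 in RCF cells and 6558 between the doses, with weights from 0.325 on the RCF arrays to 2.25 on the 9 Gy arrays. The first scan alone gave 12 genes at least 2-fold at 9 Gy and 32 between the doses, 16 higher and 16 lower at 23 Gy, against 15 and 5. It called 1762 genes up and 791 down at 9 Gy, against 2061 and 1754. Slide 1 alone gave 7243 changed genes at 9 Gy and 14631 at 23 Gy. The block by slide was not run.

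The same-dye comparison, which set slide 2 against slide 1 except between the doses, gave 6444 changed genes at 9 Gy, 12727 in RCF cells and 4198 between the doses, and 273, 347 and 492 at least 2-fold at 9 Gy, 23 Gy and in RCF cells. At 9 Gy 251 of these rose and 22 fell, against 3 and 17 within arrays, and at 23 Gy 233 rose and 114 fell, against 37 and 142. In it the median of MHC class I presentation was -0.02 at 9 Gy and -0.09 at 23 Gy, and that of ribosomal proteins -0.04 at 9 Gy. In it the correlations across genes, 0.85 between 9 Gy and 23 Gy and 0.41 between 9 Gy and RCF, carry no weight, because both sides share a term by construction, the 9 Gy difference in the first and the pair of slides in the second. LogRatio gave 0.14 for the latter. Leaving out 1 array left a group with a single array, assumed to vary like the others, and gave 140 to 316 changed genes at 9 Gy, 2770 to 3409 at 23 Gy, 5701 to 14450 in RCF cells and 0 to 2 between the doses, where a count of 0 stood beside 3565 to 4173 genes at an unadjusted p under 0.05. The same step gave 17 to 22, 154 to 178, 197 to 785 and 0 to 2 genes at least 2-fold. Signal over background limits what can be said of dim genes, and with 2 arrays per group small changes cannot be called with a stable count.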

Other observations

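The contractile and acute phase lists and the groups of genes by symbol were all chosen after the data had been seen, and the predictions for both lists were written before their values were seen. Histone classes were also compared after the data had been seen.

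No test compared the histone classes with each other, and with an estimated correlation 0 of them were called in RCF cells (adjusted p = 0.165 for H1, H2A, H2B and H4, adjusted p = 0.0779 for H3). Against cells at 24 h after 9 Gy, 15 of 18 H2B genes rose and 1 fell, with a median log2 ratio of 1.09, and 10 of 14 H2A genes rose and 0 fell, with a median of 0.55. Values of single H2B genes depended on the probe. H2BC26 read -0.26 and -0.37 on the RCF arrays at the probe used, and 1.205 at its other probe. H2BC5 read -0.07 and -0.11 at the probe used, and 1.2 at its other probe. Of 8 H1 genes 5 rose and 0 fell, with a median of 0.37. In the same contrast, 14 of 16 H3 genes fell and 0 rose, with a median of -0.50, and 6 of 12 H4 genes fell and 0 rose, with a median of -0.36. These directions were the same between RNAs in 1 dye on different slides, at 1.28 for H2B, 0.43 for H2A, 0.18 for H1, -0.42 for H3 and -0.44 for H4, and under median centring and scaling between arrays. At 24 h after 9 Gy the medians against untreated cells were -0.43 for H1 (5 of 8 fell), -0.58 for H2B (15 of 18), -0.67 for H2A (11 of 14), -0.21 for H3 (9 of 16) and -1.18 for H4 (9 of 12), and 0 genes rose. With an estimated correlation H1 (adjusted p = 0.101) and H2B (adjusted p = 0.0628) were not called there, and the same-dye median of H3 was -0.06. In the indirect contrast of RCF with untreated cells H2B genes had a median of 0.70, H1 genes of 0.01, H3 genes of -0.79 and H4 genes of -1.47, while H2A genes had one of -0.17 that turned to 0.08 under median centring.

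Genes were also grouped by the letters their symbols share, in 282 groups of at least 8 genes, and tested with camera. In RCF cells 13 groups were called up and 5 down, and in each direct comparison 0 groups were called with an estimated correlation. With 3 residual degrees of freedom and 282 groups, that test had little power. Among HLA genes the direction was uniform, with 17 of 22 genes up, 0 down and a median log2 ratio of 1.03 (adjusted p = 1.6e-08, adjusted p = 0.872 with an estimated correlation). They included class II genes, which present extracellular peptides and are named here after their values were seen, such as HLA-DPA1 (1.35), HLA-DRB1 (1.25) and HLA-DRA (0.97). Among 9 PSG genes, which encode pregnancy-specific glycoproteins of nearly identical sequence, 3 rose and 0 fell, with a median of 1.32 (adjusted p = 0.0486, adjusted p = 0.872 with an estimated correlation). Among 412 ZNF genes for zinc finger proteins 99 rose and 17 fell, with a median of 0.11 (adjusted p = 0.000437, adjusted p = 0.872 with an estimated correlation). Among 50 MRPL genes for mitochondrial ribosomal proteins 5 rose and 22 fell, with a median of -0.14 (adjusted p = 0.00458, adjusted p = 0.872 with an estimated correlation). At 23 Gy, 8 of 11 DOCK genes, which activate small GTPases, rose and 1 fell, with a median of 0.49 (adjusted p = 0.0478, adjusted p = 0.96 with an estimated correlation). At 9 Gy, 8 of 12 metallothionein genes fell and 1 rose, with a median of -0.31 that turned to 0.14 under median centring (adjusted p = 0.0154, adjusted p = 0.924 with an estimated correlation).

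CNN1 and ACTA2, both smooth muscle genes, rose at 23 Gy, and a rise of other contractile genes was tested as a hypothesis. The median log2 ratio of 22 other contractile genes was 0.14, of which 11 rose and 2 fell, and camera's p was 0.0709 (adjusted p = 0.417 with an estimated correlation). The value lies between the bounds set for a shared rise and for none, so the test left the hypothesis open. Between RNAs in the same dye, but on different slides, their median was -0.05.

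SAA1 and SAA2 rose in RCF cells, and a rise of other acute phase genes was tested as a hypothesis. The median log2 ratio of 17 other acute phase genes was 0.18, of which 3 rose, and camera's p was 0.00103 (adjusted p = 0.799 with an estimated correlation). The median again lies between both bounds. CFB and C1R, complement genes named here after their values were seen, were at 1.98 and 1.00.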
